A study of Methylobacter tundripaludum 21/22 with 8 samples.

How the data were processed

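The data were RNA-seq read counts from 8 liquid cultures of a Methylobacter tundripaludum 21/22 mutant that lacks mbaI, the gene for an acyl-homoserine lactone (AHL) synthase. Per the labels' protocols, cultures were grown on methane at 18 °C, without or with 1 uM of the AHL 3-OH-C10-HSL, and were taken in log phase at 48 h or in stationary phase at 68 h. Total RNA was depleted of rRNA and sequenced as single reads of 50 nt. Each of the 4 groups held 2 cultures, which the labels call biological replicates, so p-values measure only the spread between cultures of one group. The signal, the growth phase and the replicate number of each culture were taken from its label.

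The deposited values were whole-number counts of reads per gene, with no normalization. Per the submitters' processing notes, BWA 0.7.12-r1044, SAMtools 1.2-232, HTSeq, DESeq2 1.2.10 and R 3.3.0 were used, with no role stated for any of them. The genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Antisense, overlapping and near-identical genes could therefore not be told apart from their partners. The files do not pair the gene IDs with names or products. Only mbaI, which the labels tie to T451DRAFT_0796, is called by a name, and at most 2 IDs that rose and 2 that fell are printed for a comparison, apart from mbaI, the genes numbered near it and the most abundant gene. Locus numbers were read as an order along the annotation and give no distance in base pairs.

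Libraries held 13936075 to 19705667 counts over 4043 genes. Genes with low counts were removed with the filterByExpr defaults of edgeR 4.0.16 in R 4.3.3 (minimum count 10), which left 4024. Counts were scaled by the TMM method and fitted with the edgeR quasi-likelihood model with 1 mean per group, so that all 8 cultures shared 1 estimate of the spread. From this fit came the effect of the signal in log phase, in stationary phase and averaged over both, the difference of the effect between the phases, and the change from log to stationary phase without and with signal. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p below 0.05 were called. All adjusted p-values of single genes come from edgeR unless another tool is named. The standard error of a log2 fold change was approximated as its size divided by the square root of the F statistic. CPM values were computed on TMM-scaled library sizes and are given as mean ± SD over n = 2 cultures. Intervals for counts and for ratios of summed counts are exact intervals at 95% and cover counting error only.

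Before the data were examined, the groups, the fit, the first set of alternative settings, the rule for named genes and 28 gene lists were fixed. The rule took mbaI and the 2 numbered genes of the table on either side, the called genes with the largest fold change, a mean of at least 10 CPM in the higher group and, except for the difference between phases, replicates that did not overlap between the groups, up to 10 per direction (5 for the difference and for the growth phase change with signal), and the 5 most abundant genes. Of these selections, the first 2 per direction are printed. Without product names 1 of the 28 lists was usable, the genes within 20 locus numbers of mbaI. It was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, and again with an estimated correlation.

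The model was tested on simulated counts drawn from 1 overall mean per gene and from the library sizes and dispersions of these libraries. Beyond the genes set to change, the simulated groups did not differ, so there was no wide growth phase change. Simulated cultures of one number shared no difference, unlike the real log cultures. The shares below may therefore not hold for the real comparisons. For the signal in log phase, 86.6% of simulated genes with a 2-fold change and 23.9% of those with a 1.5-fold change were recovered among 4023 genes. In stationary phase the shares were 89.6% and 31.3% among 4021 genes. For the difference of the effect between phases only 31.3% of 2-fold and 92.4% of 4-fold changes were recovered among 4022 genes. Unchanged genes made up 5.41% of the simulated calls in log phase and 9.82% in stationary phase. No pair of replicates was a repeat of one library, since their counts differed by a chi-square of 22.7 to 109 per degree of freedom. It was 108 and 109 in log phase without and with signal, and 42.1 and 22.7 in stationary phase. Averaged over the pairs without and with signal, the replicate differences had an SD across genes of 0.404 in log phase and 0.159 in stationary phase. This average keeps what the 2 pairs share, and their differences correlated at 0.873 in log phase and 0.304 in stationary phase. The spread shared by both phases may be too small for log phase and too large for stationary phase. For the signal in log phase this is open, because the fit counts the shared difference as spread.

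Alternatives fixed in advance were RLE size factors, library totals without a composition factor, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, a replicate block, only the 2 groups compared, an added 2-fold minimum, and each culture left out in turn. Alternatives chosen after the data were seen were a replicate block within each phase, the log cultures numbered 2 left out, and one signal term beside a phase term.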

Results

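Transcript levels were measured in 8 cultures of the mbaI deletion mutant of Methylobacter tundripaludum 21/22, an aerobic bacterium that lives on methane. Quorum sensing is communication between bacteria by released small molecules, here an acyl-homoserine lactone that the mutant cannot make because its synthase gene is deleted. The signal, 3-OH-C10-HSL, was added from outside at 1 uM or left out, and cultures were taken in log phase (48 h) or stationary phase (68 h), with 2 cultures in each of 4 groups. Libraries held 13936075 to 19705667 counts, a ratio of 1.41 between the deepest and the shallowest. The most abundant gene, T451DRAFT_1629, took 4.42% to 8.95% of a library. Growth phase set the main pattern. The first principal component held 89.9% of the variance and placed log cultures between −51.3 and −33.8 and stationary cultures between 37.1 and 47.9. On this axis the log cultures numbered 2 (−33.8 and −36.4) lay nearer to the stationary cultures than those numbered 1 (−50 and −51.3), without and with signal alike. The stationary cultures with signal (37.1 and 39.1) lay nearer to the log cultures than those without signal (47.9 and 47.4).

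Counts at mbaI (T451DRAFT_0796), the deleted gene, were near 0 without signal and higher with it. In log phase 2 and 3 counts were found without signal and 219 and 396 with signal. In stationary phase the counts were 5 and 4 without and 119 and 165 with signal. The depth-scaled ratio with signal to without was 109 in log phase (95% interval 46.2 to 335) and 25.6 in stationary phase (13.3 to 56.5). These intervals come from summed counts and cover counting error only, not the spread between cultures. All 4 cultures with signal lay above all 4 without (two-sided exact permutation test, p = 0.0286, the smallest that 70 splits allow). These splits ignored growth phase. Splits within each phase would be fewer, and their smallest possible p would be larger. The edgeR log2 fold changes were 6.69 ± 0.465 (SE, adjusted p = 0.000427) and 4.64 ± 0.443 (adjusted p = 0.00246). The extent of the deletion within the gene is not given in the sources used here, so the reads were not placed inside or outside the deleted part.

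The question of the log phase comparison was which genes respond to the signal in growing cells. With the signal, the genes numbered 0802 to 0815, after mbaI, rose, with these bounds set after the values were seen. T451DRAFT_0803 went from 2.82 ± 0.523 to 300.4 ± 24.1 CPM, a log2 fold change of 6.72 ± 0.207 (SE, adjusted p = 7.62e-06). T451DRAFT_0802 went from 5.5 ± 3.84 to 278 ± 36.1 CPM (log2 fold change 5.65 ± 0.445, adjusted p = 0.000824), a call that ended with only the 2 groups compared (adjusted p = 0.0584). Among all 4024 genes 51 rose, 41 of them at least 2-fold, and 20 with only the 2 groups compared. Log replicates differed more than stationary ones (SD across genes of the pairs' mean difference 0.404 against 0.159), so the shared spread may be too small there. However, log cultures of one number shared a difference (r = 0.873 between the groups), which the fit without a block counts as spread. Whether log phase had too many or too few calls is therefore open. In the main edgeR fit 0 genes fell, against 29 with lower levels at an unadjusted p below 0.05, while DESeq2 called 2 lower and limma-voom 0. An edgeR fit with a replicate block within phase, chosen after the data were seen, called 121 higher and 47 lower. The absence of falling genes therefore depended on the model.

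Of the 34 tested genes within 20 locus numbers of mbaI, 15 rose in log phase, or 16 when adjusted over the list alone. The 14 genes numbered 0802 to 0815, the longest run of calls, with bounds set after the values were seen, all rose, with log2 fold changes from 1.29 to 6.72 and a median of 2.52, while the median of the whole list was 0.12. On the other side, T451DRAFT_0794 rose from 13.8 ± 4.8 to 55.9 ± 5.84 CPM (log2 fold change 2.01 ± 0.279, adjusted p = 0.0173). This call ended without the log culture with signal numbered 2, without either stationary culture with signal, or with only the 2 groups compared (highest adjusted p 0.171). T451DRAFT_0798, on the near side of the run, stood at 173 ± 29 CPM without and 265 ± 52.5 CPM with signal and did not pass (log2 fold change 0.62 ± 0.19, adjusted p = 0.578). T451DRAFT_0792 stood at 64 ± 16.2 and 63.7 ± 6.12 CPM (adjusted p = 1), and the 17 list members numbered below 0794 lay between −0.79 and 0.22 on the log2 scale without a call. The list stood above other genes by camera (p = 6.76e-34 with the preset correlation, p = 0.00508 with an estimated correlation).

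**Figure D1:**
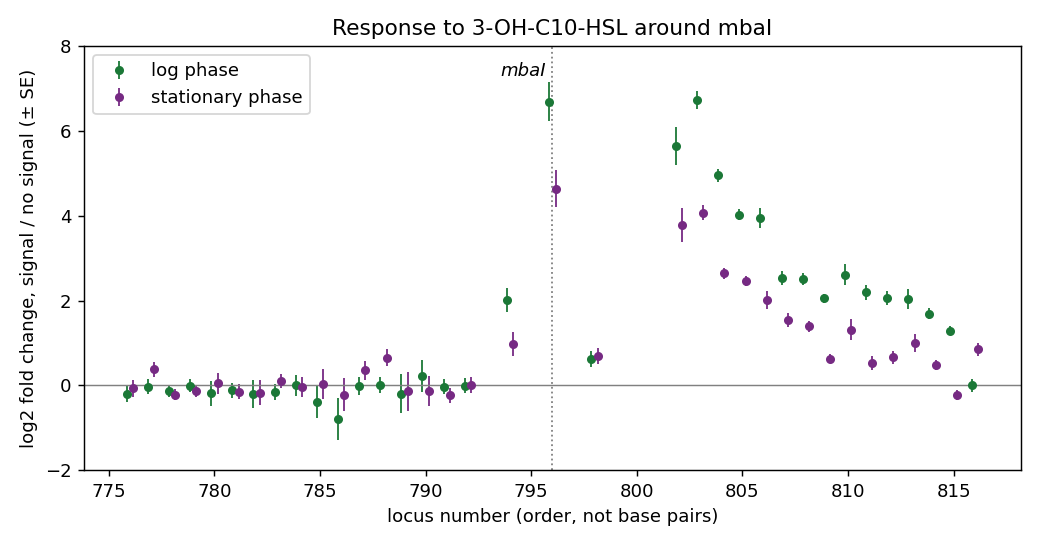
Log2 fold change with signal (y axis, ± SE, n = 2 cultures a group) for the tested genes within 20 locus numbers of mbaI and mbaI itself (x axis, locus number, not distance), in log phase (green) and stationary phase (purple). Genes numbered 802 to 815 lay between 1.29 and 6.72 in log phase, and those below 794 between −0.79 and 0.22.

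In stationary phase the same question was asked of stationary cultures. T451DRAFT_1245 fell from 1210 ± 99.4 to 9.58 ± 2.46 CPM with signal, a log2 fold change of −6.98 ± 0.211 (SE, adjusted p = 2.04e-05). T451DRAFT_1246 fell from 5560 ± 252 to 57.4 ± 57.1 CPM (log2 fold change −6.59 ± 0.875, adjusted p = 0.00921), and its cultures with signal stood apart, at 17 and 97.8 CPM. T451DRAFT_0803 rose from 13.5 ± 1.55 to 225 ± 30.4 CPM (log2 fold change 4.06 ± 0.177, adjusted p = 0.000114). T451DRAFT_0802 rose from 14 ± 1.94 to 192 ± 18.8 CPM (log2 fold change 3.78 ± 0.403, adjusted p = 0.0034), a call that ended without the culture without signal numbered 1 (adjusted p = 0.0587).

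Altogether 134 genes rose and 77 fell with the signal in stationary phase, of which 40 and 26 changed at least 2-fold. Of the mbaI neighbours 10 of 34 rose, or 17 when adjusted over the list alone. Genes numbered 0802 to 0815 had a median log2 fold change of 1.35, and 9 of the 14 rose. The list stood above other genes with the preset correlation (p = 3.67e-08), and this call ended with an estimated correlation (p = 0.066). T451DRAFT_0794 (0.98 ± 0.274, adjusted p = 0.0907) and T451DRAFT_0798 (0.70 ± 0.191, adjusted p = 0.0849) did not pass on the log2 scale, and T451DRAFT_0792 stood at 34.7 ± 0.636 without and 34.9 ± 2.88 CPM with signal. The number and balance of calls depended on scaling and on the estimate of spread. Stationary replicates differed less than log ones (SD across genes of the pairs' mean difference 0.159 against 0.404). The shared spread may therefore give too few calls in stationary phase. Library totals alone moved the median of all genes to 0.22 on the log2 scale and called 405 higher and 37 lower, RLE factors called 96 and 95, and a fit of the stationary cultures alone called 584 and 506. A replicate block called 203 and 169, and a block within phase, chosen after the data were seen, called 904 and 951. Without the stationary culture without signal numbered 1 or 2 there were 54 or 47 calls, and without that with signal numbered 1 or 2 there were 38 or 53.

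**Figure D2:**
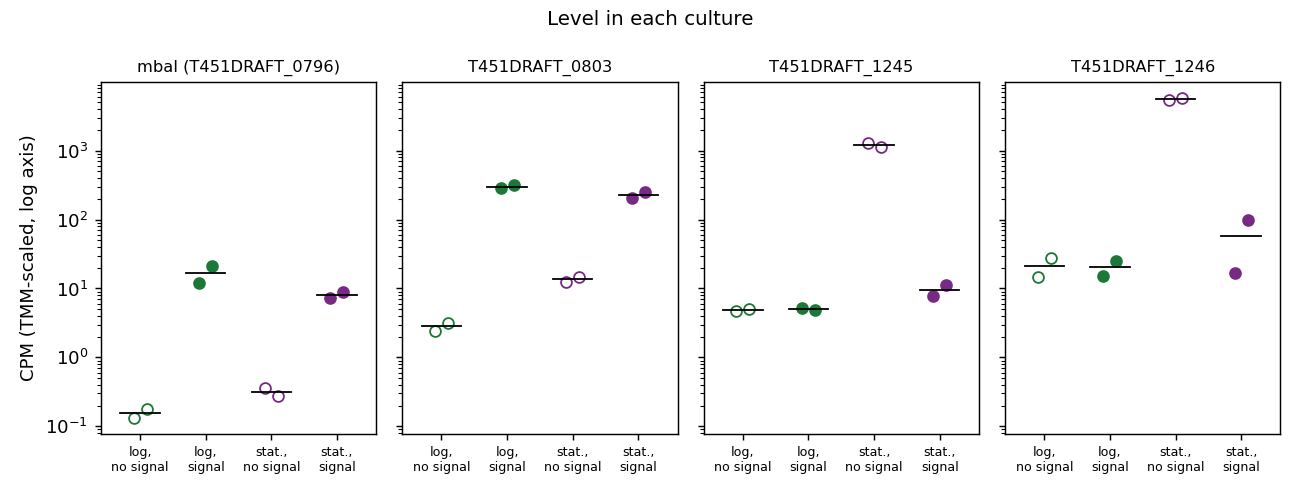
TMM-scaled CPM of 4 genes in each of 8 cultures (y axis, log scale; points, cultures; bars, means of 2; open points, no signal). T451DRAFT_1245 reached 1280 and 1140 CPM in the stationary cultures without signal and 7.84 and 11.3 CPM in those with signal.

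Averaged over both phases, with 4 cultures on each side, the signal raised 59 genes and lowered 16, of which 32 and 7 changed at least 2-fold. T451DRAFT_0803 (log2 fold change 5.39 ± 0.136, adjusted p = 2.22e-06) and T451DRAFT_0802 (4.72 ± 0.3, adjusted p = 0.000185) rose. T451DRAFT_1198 fell by 1.46 ± 0.147 on the log2 scale (adjusted p = 0.00228) and T451DRAFT_1319 by 1.10 ± 0.0698 (adjusted p = 0.000185). In log phase alone these last genes were at −0.46 and −0.32, and in stationary phase alone at −2.46 and −1.88. Of the mbaI neighbours 15 of 34 rose on average, or 17 when adjusted over the list alone (camera p = 2.92e-16, and p = 0.0202 with an estimated correlation). With one signal term beside a phase term, 31 genes were called, all higher, and the calls of T451DRAFT_1198 and T451DRAFT_1319 ended (adjusted p = 0.251 and 0.239). Library totals alone called 115 higher and 12 lower, with the median of all genes at 0.11, DESeq2 called 210 genes and a fit without the log cultures numbered 2, chosen after the data were seen, called 232. Without the stationary culture without signal numbered 2 there were 45 calls, and without that with signal numbered 1 or 2 there were 43 or 44.

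The difference between phases was tested as the stationary effect of the signal minus the log effect. The effect was lower in stationary phase for 38 genes and higher for 9. T451DRAFT_1245 had the strongest difference, −7.02 ± 0.274 on the log2 scale (adjusted p = 0.000123), since its level in log phase was 4.84 ± 0.183 CPM without and 4.99 ± 0.212 CPM with signal. T451DRAFT_1246 differed by −6.51 ± 1.08 (adjusted p = 0.0439), with 21.3 ± 9.28 and 20.2 ± 6.95 CPM in log phase. T451DRAFT_3973 (1.49 ± 0.186, adjusted p = 0.0117) and T451DRAFT_3222 (1.35 ± 0.153, adjusted p = 0.00789) had a higher effect in stationary phase.

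Of these 47 genes, 9 rose with the signal in both phases, 8 passed the test only in log phase, where they rose, 13 fell and 9 rose with a call in stationary phase alone, and 8 rose in log phase and fell in stationary phase. The last 8 had log2 fold changes from 0.82 to 1.01 in log phase and from −1.54 to −0.61 in stationary phase. At mbaI itself the difference was −2.05 ± 0.883 and did not pass (adjusted p = 0.455). Of the mbaI neighbours 9 of 34 had a lower effect in stationary phase, all of them numbered 0802 to 0815, or 14 lower and 1 higher when adjusted over the list alone (camera p = 1.64e-07, and p = 0.0754 with an estimated correlation, which ended the call). Library totals alone gave 35 higher and 33 lower, with the median of all genes at 0.23. The call of T451DRAFT_1246 ended without either culture without signal of either phase or without the log culture with signal numbered 2 (highest adjusted p 0.155), while its log2 difference stayed between −8.27 and −5.75 over all alternatives. That of T451DRAFT_3973 ended without the stationary culture without signal numbered 1 or either stationary culture with signal (0.0925), and that of T451DRAFT_3222 without any one stationary culture (0.0773).

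The phases shared 34 called genes for the signal, from contrasts of different libraries in one fit with a shared estimate of the spread, which can itself raise the overlap. In both phases 26 rose, against 1.7 for independent lists, and 8 rose in log phase and fell in stationary phase, against 0.976. These expected values take genes as independent. The 8 lay in runs of neighbouring genes, with 3, 2 and 3 of them to a run. Another 17 were called in log phase alone and 177 in stationary phase alone. Of the 26 that rose in both, 24 had the smaller log2 fold change in stationary phase. Across all genes the log2 fold changes correlated with Pearson r = 0.389, genes not being independent replicates.

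**Figure D3:**
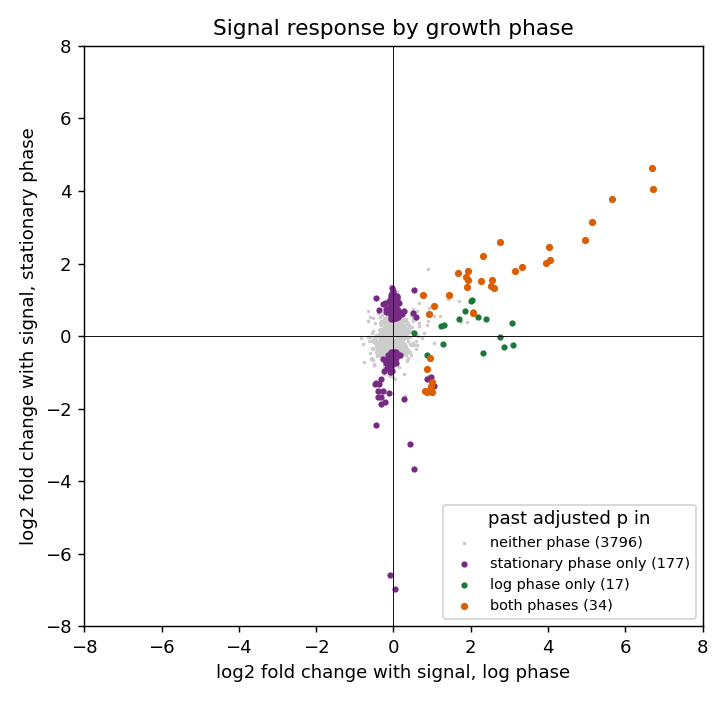
Log2 fold change with signal in log phase (x axis) against stationary phase (y axis) for 4024 genes, coloured by the phase in which the adjusted p was below 0.05. Of the 34 genes called in both phases, 26 lay in the upper right, higher in both, and 8 in the lower right.

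Between log and stationary phase without signal most of the transcriptome changed. T451DRAFT_2779 rose from 8.58 ± 0.411 to 4340 ± 873 CPM (log2 fold change 8.98 ± 0.227, adjusted p = 4.69e-06). T451DRAFT_1246 rose from 21.3 ± 9.28 to 5560 ± 252 CPM (8.02 ± 0.936, adjusted p = 0.000194). T451DRAFT_3276 fell from 542 ± 238 to 13.4 ± 1.65 CPM (−5.34 ± 0.431, adjusted p = 3.77e-05), and T451DRAFT_1309 from 1280 ± 253 to 39.7 ± 2.5 CPM (−5.01 ± 0.217, adjusted p = 6.43e-06). In all, 1483 genes rose and 1549 fell, of which 917 and 947 changed at least 2-fold. Of the mbaI neighbours 20 rose and 3 fell, also when adjusted over the list alone, and 11 of the 14 genes numbered 0802 to 0815 rose in the absence of added signal (camera p = 0.000925 for the list, and p = 0.206 with an estimated correlation, which ended the call).

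With the signal the growth phase change was similar in size and number. T451DRAFT_2779 rose from 9.09 ± 0.607 to 2890 ± 314 CPM (log2 fold change 8.31 ± 0.221, adjusted p = 7.45e-06), and T451DRAFT_3835 from 270.3 ± 104 to 7000 ± 185 CPM (4.70 ± 0.435, adjusted p = 8.32e-05). T451DRAFT_1309 fell from 1140 ± 159 to 25.8 ± 4.21 CPM (−5.47 ± 0.222, adjusted p = 7.72e-06), and T451DRAFT_3267 from 137 ± 55 to 4.43 ± 1.55 CPM (−4.94 ± 0.589, adjusted p = 0.000258). In all, 1501 genes rose and 1515 fell. The run numbered 0802 to 0815 went the other way from its course without signal, with 11 of 14 genes lower in stationary phase. Of the mbaI neighbours 13 rose and 14 fell, also when adjusted over the list alone, and the list as a whole did not stand apart (camera p = 0.957, and p = 0.982 with an estimated correlation), with a median of −0.20 and a mean of 0.089 on the log2 scale. Called in both growth phase comparisons were 2767 genes, 1337 higher and 1405 lower in both, against 553 and 583 for independent lists. The other 25 rose in stationary phase without signal and fell with it, and 0 went the opposite way. Across all genes r was 0.955. Library totals alone called 1728 higher and 1252 lower with signal, with the median of all genes at 0.27.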

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

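All tests of explanations in this part were chosen after the results were seen, while the test of the difference between phases was planned. That test found an effect of the signal that was lower in stationary phase for 38 genes and higher for 9. Among the named genes the difference was −7.02 on the log2 scale for T451DRAFT_1245 and −6.51 for T451DRAFT_1246, which stood at 9.58 and 57.4 CPM in stationary cultures with signal against 4.99 and 20.2 CPM in log cultures with signal. It was −2.66 for T451DRAFT_0803 (adjusted p = 0.00383), which rose by 6.72 in log phase and 4.06 in stationary phase. The genes printed as lower on average differed by −2.0 (adjusted p = 0.024) and −1.56 (adjusted p = 0.00333). T451DRAFT_3973 (1.49) and T451DRAFT_3222 (1.35) differed the other way. The 47 calls became 24 and 17 without the stationary culture without signal numbered 1 and 2, and 16 and 21 without that with signal numbered 1 and 2. DESeq2 on all cultures gave 89 lower and 39 higher, limma-voom 38 and 8. With library totals only the balance ended, at 33 lower and 35 higher, with the median of all genes at 0.23. It also ended with a replicate block within phase, chosen after the data were seen, at 529 lower and 563 higher.

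The 8 genes that rose with the signal in log phase and fell with it in stationary phase passed both tests in 8 of 8 cases with DESeq2 and with limma-voom. They lay in runs of neighbouring genes, with 3, 2 and 3 of them to a run, and may be fewer separate responses. Without either stationary culture without signal 1 passed both adjusted tests, without either with signal 2, and without single log cultures 3 to 6, as the median SE went from 0.118 to between 0.128 and 0.148 in log phase and from 0.121 to between 0.111 and 0.168 in stationary phase. In each of these fits 8 of 8 kept opposite signs, with log2 fold changes from 0.72 to 1.27 in log phase and from −1.63 to −0.52 in stationary phase. Their cultures with and without signal did not overlap in either phase, so leaving 1 out could hardly turn a sign. The sizes of the changes say more than the signs. Without any one culture they stayed at 0.72 or more in log phase and at −0.52 or lower in stationary phase. For these 8 genes this argues against a single library as the whole cause of the pattern. The 2-fold minimum left 2, and edgeR with only the 2 groups compared left 0, against 8 at an unadjusted p below 0.05. When genes were selected anew with library totals only, 8 genes switched past all tests, 6 of them among these 8, and 7 of the 8 with RLE, which argues against the choice among these scalings as the whole cause of the switch. A dependence of the signal response on growth phase may be the explanation, and the design does not part phase from sampling time.

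Genes called for the signal in stationary phase and not in log phase tended to move against their growth phase change. Of these 177 genes, 139 (78.5%, 95% interval 71.7% to 84.3%, genes taken as independent) had opposite signs for the signal in stationary phase and for the phase change with signal, against 60.7% of the other genes. Both contrasts use the same stationary cultures with signal on their higher side, so their signs are not independent. Error in these cultures would push the signs to agree rather than to differ, and the interval does not cover this. Selected anew with library totals only, 404 genes had a share of 71.3% (66.6% to 75.7%) against 50.9% of the others, which argues against the normalization as the whole cause. A candidate explanation is that the stationary cultures with signal were at an earlier growth state. On the first principal component they lay nearer to the log cultures (37.1 and 39.1) than those without signal (47.9 and 47.4). Either an earlier growth state or an effect of the signal on these genes could give this, and the 2 cannot be told apart. Set against the difference between the log cultures numbered 2 and 1, taken as a growth axis from other libraries, 53.7% of the genes went the opposite way (46.0% to 61.2%), but that axis had the sign of the phase change in only 63.8% of them.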

How the results depend on the processing

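Alternatives named as added in the methods (blocks within phase, log cultures numbered 2 left out, one signal term) were chosen after the data were seen; the others were planned. Of 113 alternative gene counts, 82 stayed within 1.5 times the reported one. Where they did not, the cause was not tested unless stated. In log phase (51 genes) only the 2 groups compared gave 20. In stationary phase (211) library totals gave 442, DESeq2 454, only the 2 groups compared 1090, the log cultures numbered 2 left out 1046, and the 2-fold minimum 66 by its construction. For the average (75) library totals gave 127, DESeq2 210, the 2-fold minimum 39, the log cultures numbered 2 left out 232, and one signal term 31. For the difference between phases (47) DESeq2 gave 128 and the log cultures numbered 2 left out 107. The 2-fold minimum left 1864 and 1727 genes of the growth phase change without and with signal.

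Leaving out 1 culture at a time gave 35 to 50 genes in log phase, 38 to 267 in stationary phase, 43 to 73 on average, 16 to 47 for the difference, and 2658 to 3088 and 2537 to 3133 for growth phase without and with signal. The stationary count fell to 54 and 47 without the cultures without signal numbered 1 and 2, and to 38 and 53 without those with signal. The average fell to 45 without the stationary culture without signal numbered 2 and to 43 and 44 without those with signal. A lone culture was taken to vary like the other groups.

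Cultures share replicate numbers. The replicate differences correlated at 0.873 between the log groups, so log cultures of one number shared a difference. The main fit has no block and counts this difference as spread. Between the stationary groups the correlation was 0.304, and across phases it lay between −0.024 and 0.064. The numbers therefore did not pair cultures over all groups. What cultures of one number had in common within a phase is not given in the sources used here. The replicate block gave 372 genes in stationary phase (203 higher, 169 lower) and no other count beyond 1.5 times. A replicate block within phase gave 168 genes in log phase (121 higher, 47 lower), 1855 in stationary phase (904 higher, 951 lower), 1326 on average (646 higher, 680 lower) and 1092 for the difference (563 higher, 529 lower).

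The list call was lost with an estimated correlation in stationary phase (p = 0.066), the difference (p = 0.0754) and growth phase without signal (p = 0.206). For growth phase with signal, where the list did not stand apart, its direction turned without culture number 1 of either group with signal. The camera p was then 0.821 for the log and 0.856 for the stationary culture. Over all fits without a culture this p ranged from 0.786 to 0.992. Named genes kept direction and side of the threshold in 516 of 564 alternatives, lost the call in 20 and gained one in 13. The other 15 were sign changes of T451DRAFT_0792, which was called in none of them. Its log2 fold change in log phase was 0.00040 with RLE, 0.00029 with DESeq2, 0.0096 with limma-voom, 0.0043 with the replicate block, 0.00054 with only the 2 groups, 0.0059 with the block within phase, 0.17 without log cultures numbered 2, and −0.24 to 0.28 with 1 culture left out. In stationary phase it was −0.043 with RLE and with DESeq2, and −0.082 to 0.087 with 1 culture left out. An alternative without rRNA and tRNA genes was not run, because no gene types were used here.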

Other observations

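The tests in this part were chosen after the data were seen. Genes that responded to the signal lay next to each other in the table. In log phase 36 of the 51 called genes lay in 6 runs of at least 3 consecutive genes with one direction, of which the run numbered 802 to 815 with 14 genes was the longest and one of 7 genes came next. In stationary phase 62 of the 211 called genes lay in 15 runs, rising or falling. One run of 5 genes rose by 2.33 to 3.10 on the log2 scale in log phase and lay between −0.45 and 0.37 in stationary phase, with 2 of its genes past the test of the difference. Another run of 5 fell by 1.52 to 1.88 in stationary phase and lay between −0.41 and −0.28 in log phase, with all 5 past that test. The hypothesis that called genes are neighbours more often than randomly placed calls was tested by shuffling the calls 10000 times. The shuffles gave at most 3 genes in runs for log phase, against 36 (permutation p = 1e-04, the smallest they can give), and at most 10 for stationary phase, against 62 (permutation p = 1e-04). Neighbouring genes of bacteria are often transcribed together, so a run may be a single response. The shuffles break up such groups and could be exceeded by almost any list of calls. They therefore do not show that the clustering is particular to the signal.

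The log cultures numbered 2 lay closer to the stationary cultures than those numbered 1. A difference in depth is argued against, because culture 2 was deeper than culture 1 without signal and shallower with signal (log2 ratios 0.051 and −0.13), while the gene-wise differences of the pairs correlated at r = 0.873. A later growth state of these cultures may account for it, but this was left open. Their mean difference correlated across genes with the growth phase change (r = 0.574), which restates their place on the first component, since the loadings of that component correlated with the phase change at 0.99. The labels give 48 h for each of these cultures.

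Other splits of the 8 cultures were run for the signal effect over both phases, as one term beside a phase term. The real split called 31 genes, and 3 of the 34 splits that could be fitted called as many, the real one included, a share that does not exclude chance. Both others (140 and 549 genes) also set the stationary cultures with signal against those without, so they carry part of the signal contrast and the count decides little about chance. The highest, 549, is several times the real count and points to a structure of the samples. In both, the log cultures were divided by number. With the log cultures crossed instead, number 1 without and number 2 with signal on one side, the same stationary divisions called 0 genes each. With the log cultures divided by number and the stationary cultures mixed, 0 or 1 genes were called. The high counts thus came only where both divisions stood together, and why was not tested.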
